A study of Homo sapiens with 10 samples.

How the data were processed

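RNA of sorted, uncultured bone marrow cells from 2 MDS and 3 control donors was measured on 10 one-colour Affymetrix Human Gene 1.0 ST arrays, a platform named by the probe table used here. Per the labels' protocols, total RNA was isolated with a Qiagen micro-scale column kit, checked on a Bioanalyzer, amplified by single primer isothermal amplification with a NuGEN whole-transcriptome kit for very small inputs, and labelled with biotin by the Affymetrix whole-transcript terminal labelling kit. Amplification from few cells can add spread between arrays and can distort levels of short RNAs.

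The deposited table held 33297 probe sets and 10 arrays, and its values were taken as log2 expression because they ran from 1.38 to 13.91 with none at or below 0. The submitters' processing notes name only MAS 5, a method that normally gives linear values, so the scale of the table was read from the values and the authors' background correction, summarization and normalization are not given in the sources used here. The log2 values the authors deposited were used without further normalization, since array medians lay within 5.01 to 5.25. The log base was not stated either, and fold changes given here assume base 2. Because the table is on a log scale, the alternatives planned for a pseudocount did not apply.

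The probe table gave 1 gene symbol for 19460 probe sets, several for 1754 and none for 12083, and only the first kind was named. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCh38.p14, used for names and for which genes contain which others, and 19429 probe sets were matched in this way. Each gene was represented by its probe set with the highest mean over all arrays, and genes with a mean at or above the 40th percentile of all probe sets (log2 4.638) were tested, 12861 in number. XIST, TSIX, JPX, FTX and genes of the Y chromosome were left out of all tests and tables.

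Groups and replicate numbers came from the sample titles and characteristics. The design text gives 2 patients and 3 controls for 4 MDS and 6 control arrays, so equal numbers within MDS or control were taken as 1 donor. As a check of that pairing, deviations from group means were correlated across genes between the LT-HSC and ST-HSC arrays of 1 number. They gave r = 0.449 for both MDS numbers, where a pair of arrays per group fixes both to 1 value, and 0.0768, -0.0502 and -0.184 for the 3 control numbers. Control arrays of unequal numbers gave r between -0.190 and 0.243, so the check gives the pairing no support in controls. Donor means and donor blocks rest on the pairing as taken from the design text. Donors are separate people. Except for donor means, p-values of the main fit measure the spread of arrays within groups, pooled over the 4 groups. That fit treats a donor's 2 arrays as independent, also where LT-HSC and ST-HSC are compared, and donor blocks were run as alternatives.

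Tests were run with limma 3.58.1 in R 4.3.3, with 1 fit of all 4 groups, eBayes with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. The 6 comparisons were MDS against control within each gate, LT-HSC against ST-HSC within controls and within MDS, the difference of the disease effects, and MDS against control after averaging each donor's arrays. All 35 gene lists (1098 members, 993 on the array and 867 tested) were fixed before the data were examined. Lists with at least 5 tested genes were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of 1 comparison, and again with an estimated correlation, under which only the stem cell list and the basophil, eosinophil and mast-cell list within MDS passed. Comparisons that use control LT-HSC share its arrays.

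Named genes followed a rule fixed before the data were examined. It took the 10 highest and 10 lowest differences past the threshold whose groups did not overlap. Where fewer than 10 passed in all, it added the 5 highest and 5 lowest non-overlapping differences at an unadjusted p under 0.05 as values that did not pass. It further took up to 4 genes of each list described and the sort markers CD34, CD38 and THY1, and passed over small RNAs and genes whose level can read a germline allele.

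The tests were tried on simulated data for 12861 genes with 200 changed. For MDS against control LT-HSC, 1%, 80% and 99.5% of changed genes were recovered at log2 changes of 1, 2 and 4. For LT-HSC against ST-HSC in controls the shares were 6%, 89% and 99.5%, and for donor means 12%, 97% and 99.5%. False calls were 0, 4 and 11 in the first comparison, 4, 1 and 10 in the second and 3, 8 and 13 for donor means. The simulated noise was normal and independent between genes and arrays, with 1 SD per gene for all arrays. It held no correlation between a donor's arrays and no arrays that stood apart. Recovery in the real data, above all for donor means, may thus be lower. Alternatives tried were quantile normalization, no filter, a filter at the 60th percentile, testing each probe set, no intensity trend, array weights, only the groups compared, the donor as a random or fixed block, an estimated inter-gene correlation and leaving out each donor. Leaving out the control LT-HSC arrays of replicates 1 and 2 was added after seeing the data, for all comparisons but the one over both gates.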

Results

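Gene expression was measured on 10 arrays of haematopoietic stem cells sorted from bone marrow of 2 donors with myelodysplastic syndrome (MDS, a clonal blood disorder) and 3 healthy control donors. Each donor gave 2 sorted populations. Short-term haematopoietic stem cells (ST-HSC) were negative for lineage markers, CD38 and CD90 and positive for CD34, and long-term haematopoietic stem cells (LT-HSC) differed from them by being positive for CD90, the product of THY1. The 4 groups were MDS LT-HSC (2 arrays), MDS ST-HSC (2 arrays), control LT-HSC (3 arrays) and control ST-HSC (3 arrays), and this number of arrays limits the precision of every value. Median log2 values of the arrays lay between 5.01 and 5.25.

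The control LT-HSC arrays of replicates 1 and 2 stood apart from the rest. Their Spearman correlations with the other 8 arrays, computed across probe sets, were between 0.847 and 0.914, while those among the other 8 arrays were between 0.925 and 0.974. The SDs of their log2 values were 2.02 and 2.12, below the 2.16 to 2.32 of the other arrays. These arrays enter every comparison that uses control LT-HSC, and counts without them are given below for each of these except the comparison over both gates, where that count was not computed. Through the shared estimate of spread they also enter the p-values of the comparisons within ST-HSC and within MDS. Without them the control LT-HSC group has 1 array, which is assumed to vary like the other groups.

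**Figure D1:**
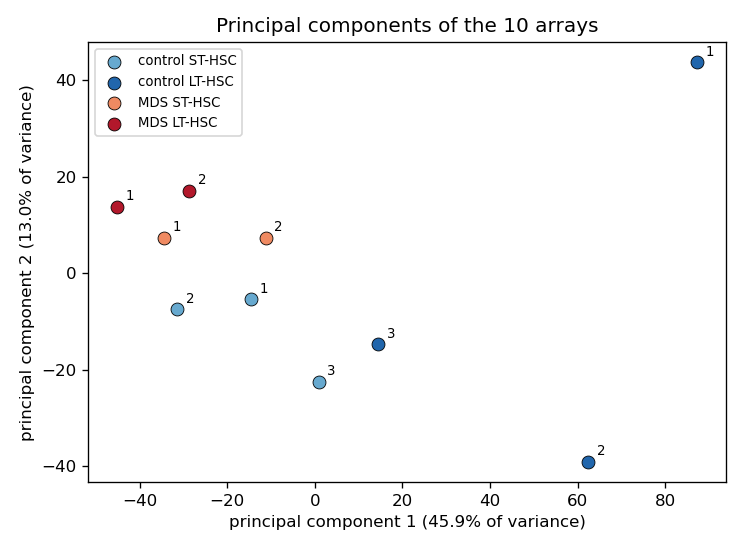
Principal components of the log2 values of the 10 arrays, with the share of variance of each component on its axis and the replicate number beside each point, coloured by group. The control LT-HSC arrays of replicates 1 and 2 lie at 87.3 and 62.4 on the first component, which holds 45.9% of the variance, and the other 8 arrays lie between -45.1 and 14.5.

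Among the sort markers, THY1 did not follow the gate in the MDS samples. In controls, THY1 was at 5.22 ± 0.33 (SD, n = 3) in LT-HSC and 4.64 ± 0.33 (SD, n = 3) in ST-HSC, a log2 difference of 0.58 ± 0.22 (SE) that did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.12). In MDS it was at 4.76 ± 0.15 (SD, n = 2) in the arrays labelled LT-HSC and 5.49 ± 0.10 (SD, n = 2) in those labelled ST-HSC, a log2 difference of -0.73 ± 0.27 (SE) opposite to the gate that did not pass either (limma, adjusted p = 1.00). THY1 lay between 4.258 and 5.582 over all arrays, near the filter level of 4.638 and the array medians of 5.01 to 5.25. At so low a level its differences are a weak guide to the gate, in controls as in MDS. Every direction drawn below from the MDS arrays uses their labels as given. CD34 differed by 0.24 ± 0.37 (log2, SE) between MDS and control LT-HSC, which did not pass (limma, adjusted p = 0.65). CD38, whose product the gate excluded, was higher in MDS LT-HSC by 2.37 ± 0.54 (log2, SE; limma, adjusted p = 0.037), a call that ended without the control LT-HSC arrays of replicates 1 and 2 (2.43; limma, adjusted p = 0.10) and without MDS replicate 1 or 2 or control replicate 1 or 2 (1.80, 2.95, 2.84 and 1.93; limma, adjusted p = 0.26, 0.11, 0.058 and 0.098).

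The first question was how MDS and control stem cells differed within the LT-HSC gate. In arrays labelled MDS LT-HSC, several granule genes and cell cycle genes were higher than in control LT-HSC, and 3 of 35 stem cell genes were lower. The lists of cell cycle and stem cell genes passed with camera, though not with an estimated correlation (adjusted p = 0.52 for each). RNASE2, a ribonuclease of eosinophil granules, was at 9.57 in MDS LT-HSC (n = 2) and 4.17 in control LT-HSC (n = 3), a log2 difference of 5.40 ± 0.49 (SE; limma, adjusted p = 0.0028). Its control LT-HSC arrays were at 4.292, 4.245 and 3.973, below the filter level of 4.638, so the size of its rise is uncertain. HLF, a transcription factor of stem cells, fell by 3.01 on the log2 scale with an SE of 0.39, from 9.37 to 6.36 (limma, adjusted p = 0.012). Of 12861 genes tested, 655 were higher and 323 lower in MDS LT-HSC at an adjusted p under 0.05, 978 in all, a split that varied with the setting (521 and 67 with the higher filter, 572 and 122 without a trend, 692 and 582 without a filter, 1667 and 1445 without control replicate 3).

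The genes with the largest rises were EPCAM, an adhesion molecule (log2 difference 6.23 ± 0.67, SE), MPO, the peroxidase of neutrophil granules (5.44), RNASE2 and its pseudogene RNASE2CP (5.16), and CPA3, a mast-cell protease (4.87). EPCAM was at 2.657, 2.963 and 3.576 in control LT-HSC, below the filter level of 4.638, so the size of its rise is uncertain. PLEK, a platelet protein, rose by 4.18, PCLAF, a partner of the replication clamp, by 4.13, and ARL15, a small GTPase, by 4.04. UBE2T, an enzyme of the Fanconi repair pathway, rose by 3.88, and MS4A3, a gene of granulocyte and monocyte progenitors, by 3.79. RNASE2 and RNASE2CP are near-identical in sequence, so which of them a probe set read is uncertain. A second EPCAM probe set gave a log2 difference of 3.11, whereas a second PCLAF probe set at a mean level of 3.72 gave -0.34.

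The genes with the largest falls besides HLF were JAML, an adhesion molecule of leukocytes (log2 difference -3.04), RMRP and RPPH1, the RNA parts of the ribonucleases MRP and P (each -1.87), and the kinase genes PRKG2 (-1.73) and PRKCH (-1.48). CRHBP, which is expressed in stem cells, fell by 1.73. The keratin-associated genes KRTAP10-5 (-1.55) and KRTAP5-2 (-1.43) and the antisense gene TMEM51-AS1 (-1.37) also fell. These last 3 were at 5.85, 7.38 and 5.91 in control LT-HSC and at 4.90, 6.76 and 4.97 in control ST-HSC. Further TMEM51-AS1 probe sets gave -0.74 and -0.33.

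Both cell cycle lists were higher. All 36 tested G2/M genes had a positive difference with a median of 1.96, and 9 rose over all genes tested (28 adjusted over the list alone), among them the cyclins CCNB2 (3.34) and CCNB1 (3.06), the spindle gene HMMR (3.23) and the kinetochore gene NDC80 (2.93). The list was higher than other genes (camera, adjusted p = 6.8e-10; adjusted p = 0.52 with an estimated correlation). Of 36 G1/S genes with a median of 1.33, 11 rose (19 adjusted over the list alone), among them the replication genes CDC45 (3.49), RFC3 (3.06), MCM4 (2.97) and MCM10 (2.55; camera, adjusted p = 3.4e-07; adjusted p = 0.52 with an estimated correlation). In MDS LT-HSC HMMR, NDC80 and MCM10 were at 8.35, 8.382 and 8.123 in replicate 1 and at 6.109, 6.337 and 6.33 in replicate 2. Of 38 DNA repair genes, 4 rose (17 adjusted over the list alone), namely FANCL (2.64) and FANCI (2.52) of the Fanconi pathway, the checkpoint kinase ATR (1.91) and the mismatch repair gene PMS2 (1.84; camera, adjusted p = 4.5e-05; adjusted p = 0.52 with an estimated correlation).

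Metabolic and RNA processing lists were higher by less. Of 51 oxidative phosphorylation genes with a median of 0.58, 4 rose (8 adjusted over the list alone), the succinate dehydrogenase genes SDHD (3.21) and SDHC (2.36), ATP5PB (1.23) and UQCRB (0.94; camera, adjusted p = 9.6e-06; adjusted p = 0.52 with an estimated correlation). Of 30 hypoxia and glycolysis genes, P4HA1 (1.58), ENO1 (1.02) and GAPDH (0.98) rose and ADM (-0.92) fell (7 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.029; adjusted p = 0.52 with an estimated correlation). Of 47 splicing factors, PRPF4 (3.21) and PRPF19 (2.01) rose, both also adjusted over the list alone (camera, adjusted p = 0.011; adjusted p = 0.60 with an estimated correlation).

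Among lineage lists, the 9 tested basophil, eosinophil and mast-cell markers had a median difference of 2.94, and RNASE2, CPA3, MS4A3 and PRG2 (2.94), which encodes an eosinophil granule protein, rose (5 adjusted over the list alone; camera, adjusted p = 0.029; adjusted p = 0.52 with an estimated correlation). PRG2 differed between the MDS donors, at 10.059 and 6.647 in LT-HSC of replicates 1 and 2. Of 35 stem cell genes, HLF, CRHBP and NRIP1 (-1.09) fell and none rose (4 lower adjusted over the list alone; camera, adjusted p = 0.040; adjusted p = 0.52 with an estimated correlation). Of 12 T-cell and NK-cell markers, with a median of -0.49, CD8B (-0.81) fell and NKG7 (1.87), a granule gene, rose (1 higher and 4 lower adjusted over the list alone; camera, adjusted p = 0.029; adjusted p = 0.52 with an estimated correlation). NKG7 was at 7.795 and 9.698 in MDS LT-HSC of replicates 1 and 2, so replicate 2 carried more of its rise. The erythroid genes HBD (2.99) and TFRC (2.59) rose as well, but their list did not pass. Neutrophil and granule markers did not pass as a list either, with 6 of 12 positive, and adjusted over the list alone 1 was higher and 3 were lower (camera, adjusted p = 0.93). Early progenitor genes did not pass as a list, with 4 of 28 higher (camera, adjusted p = 0.30).

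Genes of inflammatory signalling moved singly. TRAF6, an adaptor of Toll-like receptors, rose by 2.06 ± 0.46 (log2, SE; limma, adjusted p = 0.036) and the kinase gene PIM2 by 1.27 (limma, adjusted p = 0.043). In MDS LT-HSC TRAF6 was at 6.998 and 7.38. It was at 4.661 and 4.809 in the control LT-HSC arrays of replicates 1 and 2 and at 5.909 in that of replicate 3. Its difference without the first 2 of these control arrays was not computed. ICAM1, an adhesion gene induced by NF-kB, fell by 0.72 (limma, adjusted p = 0.046). It was at 4.217 and 4.188 in MDS LT-HSC, below the filter level of 4.638. STAT3 (2.08; limma, adjusted p = 0.054), IL1RAP (1.56; limma, adjusted p = 0.053) and CXCL8 (1.11; limma, adjusted p = 0.21) did not pass. IL1RAP was at 5.422 and 6.693 in MDS LT-HSC of replicates 1 and 2. CXCL8 was at 6.447, 8.487 and 7.043 in control LT-HSC of replicates 1, 2 and 3. None of the lists of interferon response, TNF and NF-kB targets, p53 targets or Toll-like receptor signalling passed (camera, adjusted p = 0.93, 0.88, 0.93 and 0.71).

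The count of 978 depended on the arrays. Without the control LT-HSC arrays of replicates 1 and 2 it was 46 (37 higher, 9 lower; 29 shared with the 978), and all 20 genes named by size kept their direction at 0.565 to 1.23 times their log2 difference (EPCAM 5.72, MPO 5.02, HLF -2.94), while only RNASE2 passed (5.59; limma, adjusted p = 0.039); the G2/M, G1/S, oxidative phosphorylation, DNA repair, basophil and stem cell lists still passed and the splicing, hypoxia and T-cell lists did not. Without MDS replicate 1, RNASE2 (5.46) and HLF (-3.03) did not pass (limma, adjusted p = 0.070 and 0.096), nor did the basophil and splicing lists (camera, adjusted p = 0.080 for both). The stem cell list did not pass without MDS replicate 2 (camera, adjusted p = 0.063), the hypoxia and T-cell lists without control replicate 1 (camera, adjusted p = 0.072 and 0.061), nor the basophil and stem cell lists without control replicate 3 (camera, adjusted p = 0.052 and 0.11). Leaving out MDS replicate 1 or 2 gave 9 or 73 genes, leaving out control replicate 1, 2 or 3 gave 42, 200 or 3112, a fit of the 2 groups alone gave 77, array weights gave 1891, the higher filter gave 588 and quantile normalization gave 371.

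**Figure D2:**
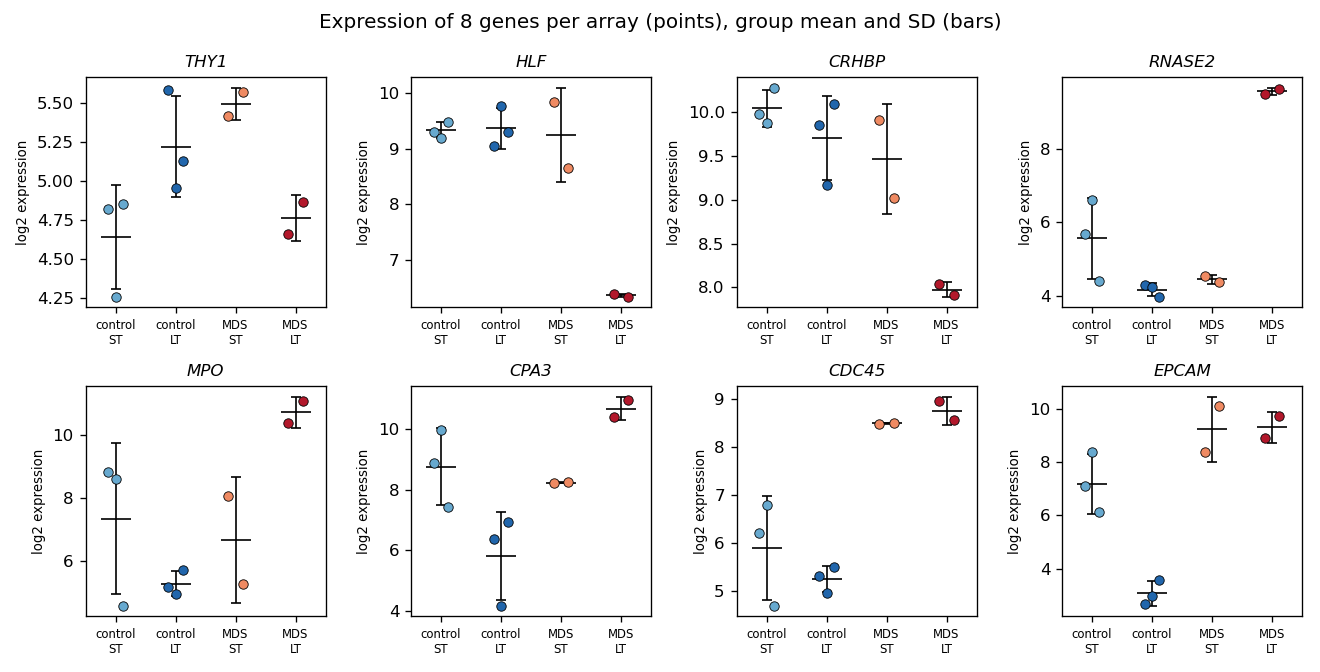
Log2 expression of 8 genes on each array (points), with the group mean and SD (bars), in ST-HSC and LT-HSC of control (n = 3) and MDS (n = 2) donors. RNASE2 was at 9.57 on average in MDS LT-HSC and between 4.17 and 5.57 in the other groups, and HLF was at 6.36 in MDS LT-HSC and between 9.25 and 9.37 in the others.

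The same comparison within the ST-HSC gate found no gene past the threshold. Cell cycle genes were again higher in MDS as lists. The 36 G2/M genes had a median difference of 0.70, with 33 positive (camera, adjusted p = 0.0026; adjusted p = 0.98 with an estimated correlation), and the 36 G1/S genes a median of 0.37, with 32 positive (camera, adjusted p = 0.0026; adjusted p = 0.98 with an estimated correlation). Adjusted over the list alone, 0 G2/M genes and 1 G1/S gene passed.

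With limma, 0 of 12861 genes passed, and 632 had an unadjusted p under 0.05. The largest differences among genes without overlap, none of which passed, were LY6G6D (2.99; limma, adjusted p = 0.18), the desmosome gene DSC2 (2.69), the replication gene CDC45 (2.59; limma, adjusted p = 0.58), the pseudogene TRPC2 (2.27) and the histone gene H3C7 (2.26). On the other side were DNTT, an enzyme of lymphoid precursors (-3.22; limma, adjusted p = 0.79), CEP19 (-1.97), FAM86B2-DT (-1.77), the receptor gene F2RL2 (-1.75) and the histone gene H3C1 (-1.57). H3C7 and H3C1 are near-identical members of one histone family, so their probe sets may read other members. DSC2 rested mainly on 1 donor, with 0.98 without MDS replicate 2 and 4.39 without MDS replicate 1, where it passed (limma, adjusted p = 0.0018), and DNTT was at -1.998 without MDS replicate 2 and FAM86B2-DT at -1.09 without control replicate 1. Array weights gave 2 genes, and leaving out MDS replicate 1 or control replicate 3 gave 3 or 1 genes. Either omission ended both list calls.

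The disease effect was then compared between the gates. RNASE2 had a larger disease difference in LT-HSC than in ST-HSC by 6.51 ± 0.69 (log2, SE; limma, adjusted p = 0.034), and no other gene passed. RNASE2 was at 4.45 in MDS ST-HSC and 5.57 in control ST-HSC. All its MDS ST-HSC and control LT-HSC arrays lay below the filter level of 4.638, so the size of this difference is uncertain. Differences of MPO (6.11), RNASE2CP (5.72), CLC, an eosinophil and basophil protein (5.41), CPA3 (5.39) and the granule protease CTSG (4.57) did not pass (limma, adjusted p between 0.28 and 0.29), nor did JAML (-3.01), HLF (-2.93), TRPC2 (-2.73), SKAP1 (-2.18) or TCEAL2 (-1.85). CLC was at 2.63 without MDS replicate 1 and 8.19 without MDS replicate 2, CTSG at 2.74 without the control LT-HSC arrays of replicates 1 and 2 and at 6.67 without control replicate 3, where it passed (limma, adjusted p = 0.031), and SKAP1 at -1.22 without control replicate 2. At an unadjusted p under 0.05 there were 2025 genes. The RNASE2 difference stayed between 6.36 and 6.71 in the settings that ended its call. The call ended with the donor as a fixed replicate block (limma, adjusted p = 0.051), without a trend (limma, adjusted p = 0.10), without the control LT-HSC arrays of replicates 1 and 2 (limma, adjusted p = 0.25), and without MDS replicate 1, MDS replicate 2 or control replicate 1 (limma, adjusted p = 0.30, 0.25 and 0.28). Without control replicate 3 there were 67 genes.

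Over both gates, averaging each donor's 2 arrays, 15 genes were higher and 9 lower in MDS, and 2629 had an unadjusted p under 0.05. CDC45, a subunit of the replicative helicase, was higher by 3.04 ± 0.30 (log2, SE; limma, adjusted p = 0.017), with 2 MDS and 3 control donors. This call and those of the other higher genes ended without control replicate 1 and with each probe set tested, where 0 were higher. The higher genes included EPCAM (4.14), PCLAF (2.50), H3C7 (2.42), the kinetochore gene ZWILCH (2.24), the splicing gene PRPF4 (2.23), the signalling gene RASGRP3 (1.98), UBXN8 (1.89), RAB2B (1.87), the sterol enzyme gene EBP (1.85) and the ribosomal protein gene RPS28 (0.73). RPPH1 fell by 1.55, and the other 8 lower genes were small nucleolar RNAs. A second EPCAM probe set gave 2.70 and a second PCLAF probe set -0.18.

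As lists over both gates, 35 of 36 G2/M genes were positive with a median of 1.25, and 25 passed adjusted over the list alone (camera, adjusted p = 3.4e-12; adjusted p = 0.84 with an estimated correlation). The largest were HMMR (2.12), CCNB2 (2.09) and CCNB1 (1.97), which did not pass over all genes. HMMR was at 7.735 and 8.35 in ST-HSC and LT-HSC of MDS replicate 1, and at 5.86 and 6.109 in those of MDS replicate 2. Of 36 G1/S genes, CDC45 rose and 15 passed adjusted over the list alone (camera, adjusted p = 1.4e-08; adjusted p = 0.84 with an estimated correlation). The lists of oxidative phosphorylation, DNA repair and hypoxia and glycolysis were also higher, with 2, 4 and 4 genes adjusted over the list alone (camera, adjusted p = 7.8e-05, 6.2e-04 and 0.011; adjusted p = 0.84 with an estimated correlation for each). The count of 24 was 145 with the donor as a random replicate block and 38 with array weights. It was 4 without a trend (1 higher, 3 lower) and 1 with each probe set tested (0 higher, 1 lower). With the random replicate block PCLAF, RASGRP3, RAB2B and EBP did not pass (limma, adjusted p = 0.085, 0.072, 0.059 and 0.083). The count was 10 without MDS replicate 1, where the DNA repair and hypoxia lists did not pass (camera, adjusted p = 0.059 for both), and 3 without control replicate 1.

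LT-HSC and ST-HSC of control donors were compared next. In LT-HSC 53 genes fell and 3 rose, a split that varied with the setting: array weights gave 620 lower and 410 higher, and leaving out control replicate 3 gave 1044 lower and 950 higher. EPCAM fell by 4.12 on the log2 scale with an SE of 0.60, from 7.19 to 3.07 (limma, adjusted p = 0.042), and ARL15 had a log2 difference of -3.56. The EPCAM level in control LT-HSC lay below the filter level of 4.638, so the size of its fall is uncertain. The falls also included the chromatin gene MIER3 (-2.89), the lipase gene PNPLA4 (-2.59), NABP2, a single-strand DNA binding protein of repair (-2.54), ZNF737 (-2.53), the ubiquitin ligase gene RNF170 (-2.50), the elongation cyclin CCNT1 (-2.43), the lipid droplet gene LDAH (-2.41) and H3C1 (-2.31). HBM, a globin (1.26), ADIRF (0.93) and IRF2BPL (0.91) rose. A second EPCAM probe set gave a log2 difference of -0.81.

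By list, DNA repair genes were lower in control LT-HSC with a median of -0.45, where 9 fell and 2 rose adjusted over the list alone, and FANCL (-2.58) and ATM (-1.81) did not pass over all genes (camera, adjusted p = 0.0057; adjusted p = 0.74 with an estimated correlation). Lists of oxidative phosphorylation, splicing factors, G2/M genes, ribosomal proteins, genes recurrently mutated in MDS and G1/S genes were lower too (camera, adjusted p = 0.0057, 0.014, 0.021, 0.035, 0.038 and 0.045; adjusted p = 0.74 with an estimated correlation for each), and adjusted over the list alone 0, 0, 0, 0, 2 and 5 of their genes fell. T-cell and NK-cell markers and NOTCH genes were higher (camera, adjusted p = 0.021 and 0.048; adjusted p = 0.74 with an estimated correlation for both), each with 2 genes adjusted over the list alone. With the donor as a fixed replicate block, 51 genes passed, 28 of them among the 56, and the G1/S and NOTCH lists did not (camera, adjusted p = 0.057 and 0.053); with the donor as a random replicate block 130 passed. Under the fixed replicate block PNPLA4, RNF170, LDAH, HBM, ADIRF and IRF2BPL no longer passed (limma, adjusted p = 0.071, 0.069, 0.052, 0.073, 0.089 and 0.087).

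Without the control LT-HSC arrays of replicates 1 and 2, 0 genes and 0 lists passed with limma and camera, though the differences of the genes named above by size kept their direction (MIER3 -2.89, NABP2 -3.31, ARL15 -3.78 and EPCAM -3.61). Without control replicate 1, 2 or 3 the counts of genes were 1, 0 and 1994, without MDS replicate 1 or 2, which enter the shared estimate of spread, 6 and 5, with array weights 1030, and with these 2 groups alone 7. Quantile normalization gave 28 genes, all lower. Without control replicate 1 only the DNA repair and oxidative phosphorylation lists of those named still passed, and without control replicate 2 the splicing, G2/M, ribosomal, G1/S and NOTCH lists did not (camera, adjusted p = 0.14, 0.58, 0.14, 0.31 and 0.14).

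**Figure D3:**
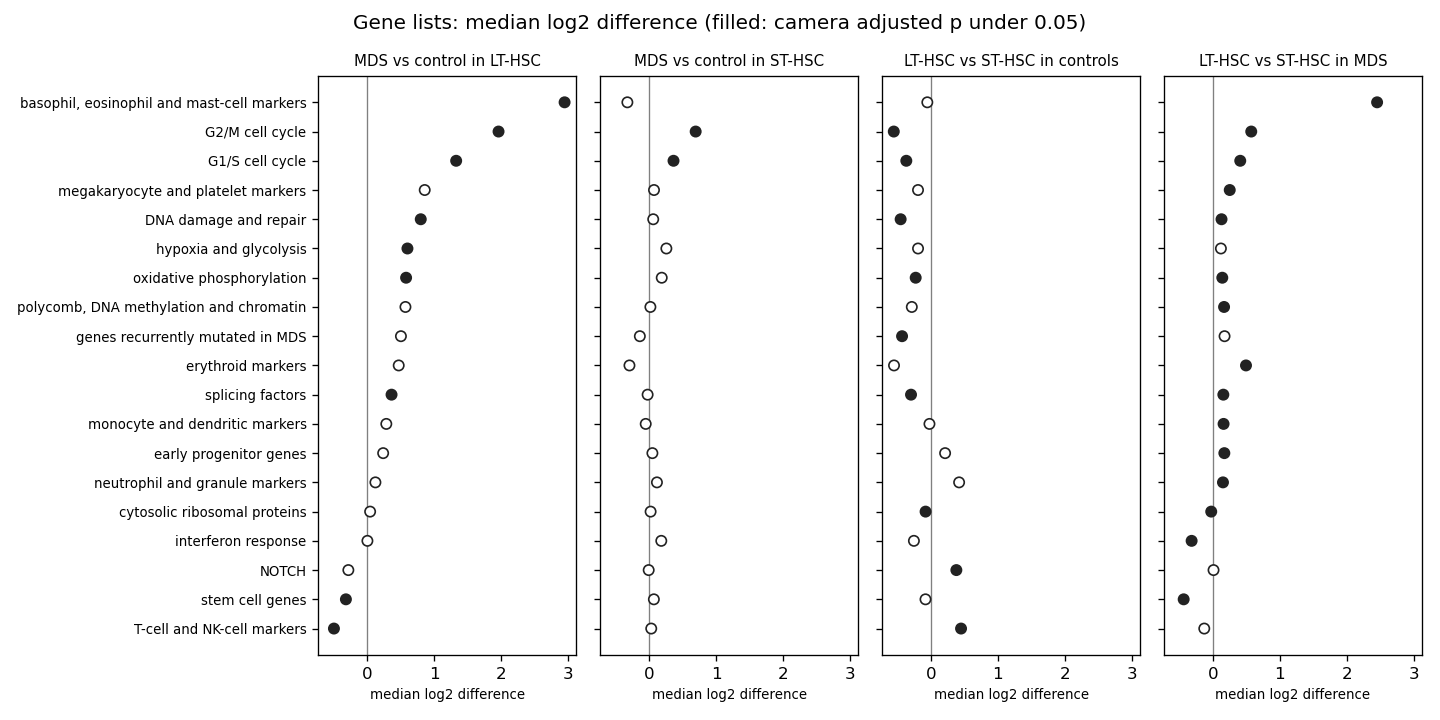
Median log2 difference of the genes of 19 lists (rows) in 4 comparisons (panels), where filled points mark lists with a camera adjusted p under 0.05 and open points the others. The G2/M list has medians of 1.96 and 0.70 for MDS against control in LT-HSC and ST-HSC, and the basophil, eosinophil and mast-cell list has medians of 2.94 for MDS against control in LT-HSC and 2.45 for LT-HSC against ST-HSC in MDS.

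Within the MDS donors, 2 genes were higher and 1 lower in the arrays labelled LT-HSC than in those labelled ST-HSC, and the list of basophil, eosinophil and mast-cell markers was higher and that of stem cell genes lower (camera, adjusted p = 0.024 and 0.018 with an estimated correlation). RNASE2 was higher by 5.11 ± 0.54 (log2, SE; limma, adjusted p = 0.030; n = 2 and 2). SERPINB10, a protease inhibitor of the bone marrow, was higher by 3.83 ± 0.48 (limma, adjusted p = 0.045), and TRPC2 fell by 2.77 with an SE of 0.31 (limma, adjusted p = 0.031). In the MDS ST-HSC arrays RNASE2 was at 4.538 and 4.366 and SERPINB10 at 4.242 and 3.702. TRPC2 was at 4.604 and 4.069 in the MDS LT-HSC arrays. All these levels lay below the filter level of 4.638, so the sizes of these differences are uncertain. Of 12861 genes these 3 passed, and 259 had an unadjusted p under 0.05. In the same arrays THY1 was lower by the value given above and CD38 differed by 1.61 ± 0.59 (SE; limma, adjusted p = 1.00).

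The 35 stem cell genes were lower in MDS arrays labelled LT-HSC with a median of -0.43 and 5 lower adjusted over the list alone, and this held with an estimated correlation (camera, adjusted p = 1.0e-12; adjusted p = 0.018 with an estimated correlation). HLF (-2.89; limma, adjusted p = 0.16) and the endothelial and stem cell gene EMCN (-2.26; limma, adjusted p = 1.00) had the largest values and did not pass over all genes. All 9 basophil, eosinophil and mast-cell markers were positive with a median of 2.45 and 5 higher adjusted over the list alone (camera, adjusted p = 3.2e-12; adjusted p = 0.024 with an estimated correlation). Besides RNASE2 these were led by CLC (5.36), MS4A3 (4.13) and PRG2 (3.59), which did not pass over all genes (limma, adjusted p = 1.00). MPO (4.06) and CTSG (3.62), granule genes of the neutrophil lineage, and JAML (-2.92), TCEAL2 (-2.06) and PREX2 (-2.06) did not pass either. Sizes differed between the donors: CLC, PRG2 and EMCN were at 2.58, 1.79 and -0.92 without MDS replicate 1 and at 8.14, 5.38 and -3.60 without MDS replicate 2, where PRG2 passed (limma, adjusted p = 0.038) and MPO was at 2.30.

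Cell cycle lists were higher in the same arrays, with all 36 G2/M genes positive at a median of 0.57 (camera, adjusted p = 9.6e-10; adjusted p = 0.45 with an estimated correlation) and 32 of 36 G1/S genes positive at a median of 0.41 (camera, adjusted p = 6.1e-06; adjusted p = 0.51 with an estimated correlation), and with 0 genes of either adjusted over the list alone. Early progenitor genes were higher with 2 genes adjusted over the list alone (camera, adjusted p = 3.2e-05; adjusted p = 0.25 with an estimated correlation); RNASE2 and MPO belong to this list as well as to a lineage list. The count of 3 genes became 1 with the donor as a fixed replicate block, where RNASE2 passed (limma, adjusted p = 0.046) and SERPINB10 (limma, adjusted p = 0.10) and TRPC2 (limma, adjusted p = 0.30) did not. It was 1 with quantile normalization, the higher filter or each probe set tested, and 0 without a trend or without control replicate 1. Without control replicates 2 and 3 it was 2 and 4, and only 1 of the 2 was among the 3. The calls of all 3 genes also ended without the control LT-HSC arrays of replicates 1 and 2, and without either MDS replicate. Without MDS replicates 1 and 2, RNASE2 was at 5.27 and 4.96, SERPINB10 at 4.61 and 3.05 and TRPC2 at -3.34 and -2.20.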

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

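The tests of exchanged labels, of mature genes within each donor, of short RNA recovery and of the host genes of the called small nucleolar RNAs were chosen after the results were seen, as was leaving out the control LT-HSC arrays of replicates 1 and 2.

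The disease effect differed between the gates by the interaction test for RNASE2, at 6.512 (log2; limma, adjusted p = 0.034), and for 12 gene lists by camera, all of which lost the call with an estimated correlation (adjusted p = 0.55). In those lists the median disease effect in LT-HSC minus that in ST-HSC, on the log2 scale, was 3.264 for basophil, eosinophil and mast-cell markers, 1.259 for G2/M genes, 0.8878 for G1/S genes, 0.7915 for DNA repair, 0.5545 for genes recurrently mutated in MDS and 0.5525 for erythroid markers. It was 0.4878 for splicing factors, 0.451 for polycomb and chromatin genes, 0.3828 for oxidative phosphorylation, -0.4303 for HOXA and HOXB genes, -0.4666 for stem cell genes and -0.528 for T-cell and NK-cell markers. Without the control LT-HSC arrays of replicates 1 and 2, the lists of genes recurrently mutated in MDS, HOXA and HOXB genes, polycomb and chromatin genes, splicing factors and T-cell and NK-cell markers did not pass (camera, adjusted p = 0.18, 0.20, 0.37, 0.17 and 0.070). Erythroid markers and stem cell genes did not pass without control replicate 3 (camera, adjusted p = 0.085 and 0.092), nor oxidative phosphorylation without MDS replicate 2 (camera, adjusted p = 0.0501).

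The 978 genes that differed between MDS and control LT-HSC may owe part of their number to the control LT-HSC arrays of replicates 1 and 2. With 1 control LT-HSC array kept at a time, assumed to vary like the other groups, replicates 1, 2 and 3 gave 3041, 1289 and 46 genes, so the smaller count with either of those arrays was 28.02 times the count with replicate 3. A difference of the donors is also open, since 73.42% of the 978 genes had the same sign in ST-HSC, which are other arrays of the same donors, against 53.6% of all genes, although genes called higher had a median of 1.74 in LT-HSC and 0.34 in ST-HSC, and genes called lower -0.89 and -0.06. The called genes, higher and lower pooled, had a median level -0.03272 log2 from that of all tested genes, which cannot part the directions. Genes called lower in MDS LT-HSC numbered 582 without a filter, 323 with the main filter and 67 with the filter at the 60th percentile. Genes called higher numbered 692, 655 and 521 in these settings. Most lower calls were thus lost with the higher filter, so low levels may contribute to them. For the higher calls low levels as a source stay undecided. No test here parts a technical difference of the control LT-HSC arrays of replicates 1 and 2 from a biological one of those donors' LT-HSC.

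In the MDS arrays labelled LT-HSC, the basophil, eosinophil and mast-cell list was higher and the stem cell list lower than in those labelled ST-HSC (camera, adjusted p = 0.024 and 0.018 with an estimated correlation). Mature neutrophils or monocytes are argued against as the whole source, because only 2 of 8 abundant genes of those cells, S100A8 and LYZ, were higher by over 1 log2 (0 of 8 in MDS replicate 1 and 2 of 8 in MDS replicate 2) and S100A9 differed by -0.11 and CSF3R by 0.12, though a small share of them in MDS replicate 2 is not excluded, as the neutrophil and monocyte lists were higher (camera, adjusted p = 0.0055 and 0.024; adjusted p = 0.45 and 0.54 with an estimated correlation) and did not pass without that donor (camera, adjusted p = 0.098 and 0.54). An exchange of the ST-HSC and LT-HSC labels in the MDS samples may contribute and stays open. THY1 in the arrays labelled LT-HSC differed by -0.7285 (log2, SE 0.27), at the low level given above, which makes it weak evidence of an exchange. Across genes, which are not independent replicates, the LT-HSC minus ST-HSC differences of controls and MDS had r = -0.224 (0.137 for the 35 stem cell genes, in the other direction). The control differences include the control LT-HSC arrays of replicates 1 and 2, and r was not computed without them. It therefore cannot part an exchange from the difference of those arrays. HLF does not part the gates in controls (9.37 and 9.33). Its 6.36 in the MDS arrays labelled LT-HSC is unlike either control gate and gives the exchange no support. RNASE2, at 9.57 in those arrays, was also unlike either control gate (4.17 in LT-HSC and 5.57 in ST-HSC). Its direction is however the one an exchange would give. In controls RNASE2 was at 4.292, 4.245 and 3.973 in LT-HSC and at 5.69, 6.611 and 4.403 in ST-HSC. RNASE2 therefore does not decide the question. More progenitors within the sorted cells, a biological difference, stays open as well, as the early progenitor list was higher (camera, unadjusted p = 5.141e-06; adjusted p = 0.25 with an estimated correlation). Eosinophils, basophils or mast cells among the sorted cells were not tested, as the 8 mature genes are of neutrophils and monocytes.

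Over both gates 8 of the 9 genes lower in MDS were small nucleolar RNAs, SNORD46, SNORD13, SNORD13P3, SNORD102, SNORD94, SNORA80E, SNORD116-1 and SNORD61, which fall outside the naming rule and were chosen after their values were seen; of the 58 SNORD and 39 SNORA genes tested none was called higher there, but in LT-HSC alone 9 and 1 were called lower and 4 and 1 higher. In the planned test of lower host gene transcription, 40 host genes had a median of 0.08312 (log2) against 0.06 for all genes, but their 52 small nucleolar RNAs had a median of only -0.15, so this wider set says little of the called ones. It is argued against for SNORA80E (-3.10) and SNORD94 (-3.29), whose hosts KHDC4 and PTCD3 differed by 0.25 (SE 0.30) and 0.57 (SE 0.39); the test over the 3 called RNAs inside a measured gene gave a host median of 0.2514, but includes SNORD13P3, a copy of SNORD13, for which the gene around it says little. SNORD13 has a promoter of its own, and for SNORD46, SNORD102, SNORD116-1 and SNORD61 no single host was measured, so host transcription stays open there. Poorer recovery or amplification of short RNAs may contribute and could not be decided, as the medians of both classes in both gates were negative with the highest at -0.1639.

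For LT-HSC against ST-HSC in controls, 10 splits of the 6 arrays exist, too few for a share under 0.05. The real split gave 56 genes, and it was the 1 split with as many, while the highest of the others gave 1. The real split and those with 1 gene kept the control LT-HSC arrays of replicates 1 and 2 on the same side. These counts therefore cannot part a difference of the gates from that of those arrays.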

How the results depend on the processing

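Leaving out the control LT-HSC arrays of replicates 1 and 2 was chosen after seeing the data. Of 1228 values of single genes under alternatives, 1216 kept their direction, 271 lost the call and 12 reversed, and of 499 values of lists 496 kept it, 145 lost the call and 3 reversed. The 1228 values include genes that had not passed with the main settings and so had no call to lose. The 271 are therefore a larger share of the calls than of the 1228. Where fewer genes or samples do not account for a change, its cause was not tested. Signal over background could not be assessed from this table, and depth plays no part in arrays. A donor left out leaves the MDS groups with 1 array each, and the set without those arrays leaves 1 control LT-HSC array; such an array is assumed to vary like the other groups. Quantile normalization moved the median of all genes between MDS and control LT-HSC from 0.07 to -0.06, and between LT-HSC and ST-HSC in controls from 0.03 to 0.11. Counts of genes and lists not given below stayed within 1.5 times. A like count does not mean the same genes. Within MDS, a fit of only the groups compared gave 3 genes, of which 1 was among the main 3. Over both gates, leaving out control replicate 3 gave 27 genes, of which 16 were among the main 24.

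For MDS against control LT-HSC (978 genes), quantile normalization gave 371, a filter at the 60th percentile 588, array weights 1891, only these groups 77, the set without the control LT-HSC arrays of replicates 1 and 2 gave 46, and leaving out a donor gave 9 to 3112. In ST-HSC (0 genes) array weights gave 2 and leaving out a donor 0 to 3. For LT-HSC against ST-HSC in controls (56 genes), quantile normalization gave 28, the 60th percentile 87, each probe set tested 37, array weights 1030, the donor as a random replicate block 130, only these groups 7, the set without those 2 arrays 0, and leaving out a donor 0 to 1994. In MDS (3 genes), quantile normalization, the 60th percentile, each probe set tested and the donor as a fixed replicate block each gave 1, no trend 0, the set without those 2 arrays 0, and leaving out a donor 0 to 4. For the difference of disease effects (1 gene), each probe set tested gave 2, no trend 0, the fixed replicate block 0, the set without those 2 arrays 0, and leaving out a donor 0 to 67. Over both gates (24 genes), each probe set tested gave 1, no trend 4, array weights 38, the donor as a random replicate block 145, and leaving out a donor 3 to 34. Blocks ended no call of a named gene or list besides those given in the comparisons and for the oxidative phosphorylation list within MDS.

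An estimated correlation left 0 lists of 9 for MDS against control LT-HSC, 0 of 2 in ST-HSC, 0 of 9 for LT-HSC against ST-HSC in controls, 2 of 15 in MDS, 0 of 12 for the difference of effects and 0 of 5 over both gates. Quantile normalization gave 4 lists for ST-HSC, 2 in controls and 6 for the difference of effects, no filter gave 9 over both gates, and the set without those 2 arrays gave 0 in controls. Leaving out a donor gave 0 to 5 lists for ST-HSC and 2 to 10 in controls.

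Values that reversed had not passed, apart from the lists. CD34 between MDS and control LT-HSC (0.24) was -0.0313 with quantile normalization, -0.24 in the set without those 2 arrays and -0.16 to 0.48 leaving out a donor. In ST-HSC, leaving out a donor gave -0.34 to 0.22 for CD34 and -0.85 to 0.12 for CD38. For the difference of effects CD34 was -0.0187 with quantile normalization, -0.18 in the set without those 2 arrays and -0.0390 to 0.53 leaving out a donor, and over both gates -0.0219 with quantile normalization and -0.15 to 0.29 leaving out a donor. Within MDS, the signed -log10 p of camera ranged from -8.11 to 1.44 for ribosomal proteins, -0.0565 to 3.67 for polycomb and chromatin genes and -0.22 to 3.64 for oxidative phosphorylation, leaving out a donor.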

Other observations

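Several lists moved within MDS that the comparisons above did not describe, each lost with an estimated correlation. In arrays labelled LT-HSC, 12 of 13 erythroid markers were positive against those labelled ST-HSC with a median of 0.50 (camera, adjusted p = 3.2e-05; adjusted p = 0.055 with an estimated correlation). APOC1 (1.64) and CA1, a carbonic anhydrase of red cells (1.62), did not pass singly, nor did HBB, a globin, whose mean of 2.48 covers a higher value in 1 donor and a lower value in the other. Of 38 interferon response genes 6 were positive, with a median of -0.31 (camera, adjusted p = 2.1e-04; adjusted p = 0.25 with an estimated correlation), and without MDS replicate 1 the list did not pass (camera, adjusted p = 0.41). BST2 (-1.03) and MX1 (-0.79) did not pass singly, nor did IFI44L (-1.37), which was lower in 1 of the 2 donors only. BST2 differed by -1.68 in MDS replicate 1 and by -0.37 in MDS replicate 2. In MDS against control LT-HSC the interferon list had a median of 0.01.

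Neutrophil and granule markers, megakaryocyte and platelet markers and monocyte and dendritic markers were higher in the same comparison (camera, adjusted p = 0.0055, 0.014 and 0.024; adjusted p = 0.45, 0.45 and 0.54 with an estimated correlation). The megakaryocyte list was led by the integrin ITGB3 (1.85) and the platelet chemokine PPBP (1.42). In MDS replicates 1 and 2 ITGB3 differed by 2.60 and 1.11, and PPBP by 0.66 and 2.18. DNA repair, splicing, polycomb and chromatin and oxidative phosphorylation lists were higher (camera, adjusted p = 0.0072, 0.025, 0.038 and 0.042; adjusted p = 0.58, 0.63, 0.61 and 0.63 with an estimated correlation), and ribosomal proteins were lower with a median of -0.02 (camera, adjusted p = 0.046; adjusted p = 0.72 with an estimated correlation). Without MDS replicate 1 the megakaryocyte, DNA repair, splicing, polycomb and ribosomal lists did not pass (camera, adjusted p = 0.81, 0.22, 0.44, 0.90 and 0.10), and without MDS replicate 2 the neutrophil, monocyte and oxidative phosphorylation lists did not (camera, adjusted p = 0.098, 0.54 and 0.73). With the donor as a fixed replicate block the oxidative phosphorylation list did not pass (camera, adjusted p = 0.058).

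Of genes recurrently mutated in MDS, PHF6 rose by 1.44 and SETBP1 fell by 0.66 in MDS against control LT-HSC (limma, adjusted p = 0.046 and 0.038). SETBP1 was at 4.423 and 4.43 in MDS LT-HSC, below the filter level of 4.638, and at 5.018 to 5.139 in control LT-HSC. EZH2 (2.43; limma, adjusted p = 0.053) and IDH2 (1.97; limma, adjusted p = 0.059) did not pass, and neither did the list (camera, adjusted p = 0.19).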
